A study of Homo sapiens with 6 samples.

How the data were processed

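The data are Affymetrix expression arrays of biotin-labelled cRNA prepared from total RNA of PMA-differentiated THP-1 macrophages, 3 arrays of cells given interferon-gamma and LPS and 3 of cells given interleukin-4, per the labels' protocols. How long the polarizing stimuli were left on is not given in the sources used here. Groups and replicate numbers were taken from the sample titles.

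The deposited values are log2 signals, 1 per probe set and array. The authors' software was MAS5, per the submitters' processing notes, which give no version. No header or label states the log base or the scaling, and both were read from the values, which run from 0 to 16.22: as powers of 2 they have a trimmed mean (2% cut at each end) between 494.8 and 496.1 on every array, as MAS5 scaling to a common target leaves them. Array medians were left unequal by this scaling (log2 6.09 to 6.58). Between 27 and 152 values per array are exactly 0, the lowest value in the table. MAS5 detection calls were not analysed here. The table analysed here holds 0 Affymetrix control probe sets, so the 3'/5' ratios and spike-in signals planned as quality measures were replaced by the array medians, the shares above the floor and the correlations between arrays. The genome build is not given in the sources used here, and no coordinates are printed.

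Probe sets were named through the platform's annotation: 41091 carry 1 gene symbol, 1801 several and 11721 none. Of the 41091, 41037 were matched by Entrez identifier to the current RefSeq gene table of assembly GRCh38.p14, which was used only for names and for the order of neighbouring genes, and 54 kept the symbol of the annotation. Probe sets with several symbols or none were not named. Tests were run in R 4.3.3 with limma 3.58.1. Values below a floor were set to it; the floor was the 40th percentile of all values pooled over the 6 arrays (log2 5.676, linear signal 51.1). It is a working limit and not a measured background. A probe set was kept where at least 3 of the 6 arrays, of either group, were above the floor. Each gene was represented by 1 probe set, without those ending in _x_at (which can match several transcripts) where the gene had another, and with the highest mean over all arrays. This left 14827 genes.

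The difference M(LPS+IFNg) minus M(IL4) was tested by lmFit and eBayes with trend and robust settings, two-sided, with 4 residual degrees of freedom per gene, and Benjamini-Hochberg adjustment over all genes. The threshold was an adjusted p of 0.05, and 2-fold counts also needed a log2 difference of at least 1. SE is the moderated standard error. Each gene's variance was drawn towards that of genes of like signal, with a median of 9.18 prior degrees of freedom against the 4 residual ones. A fold is written as "at least" where the dimmer group had an array at the floor. Gene lists were tested with camera at a preset correlation of 0.01 where at least 5 members were measured, adjusted over the 27 lists, and again with an estimated correlation and with fry. Exact tests of 3 arrays against 3 cannot go below p = 0.1 and were not used for single genes.

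The lists, the floor, the filter, the tests and the rule for named genes were fixed before the data were examined. Named genes were the measured members of a panel of 33 polarization genes; per direction, the 8 largest differences among called genes above the floor on all arrays with no overlap between groups, and the 5 largest lower-bound folds among called genes above the floor on all arrays of a single group only; and per list the 3 called members with the largest difference. This gave 113 genes. Of the panel, 29 genes were tested, 2 were under the filter, and 2 without a probe set of 1 gene symbol are not reported here. Uncharacterised loci were passed over among the largest differences. Named outside the rule, after their values were seen, were IRF8, RFXAP, RFX5, IRAK3, LYZ, HSP90B1, SH3BP2, ZC3HAV1, members of the IL-4 list checked by a further probe set, and genes of the groups and runs of neighbours added later. The match of 1 older gene symbol in the mitochondrial list was corrected after a first run, which added COXFA4 and moved the list's adjusted p from 0.046 to 0.0537.

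The procedure was tested on simulated data with the real genes' means and spreads, 14827 genes of which 200 were changed (50 per size). For M(LPS+IFNg) against M(IL4), changes of 0.5, 1, 2 and 3 log2 units were recovered in 14%, 56%, 64% and 68% of genes, and 6 of 107 calls were false. The loss at large sizes came from dim genes: of those changed by 2 log2 units, 31 of 32 bright and 1 of 18 dim genes were recovered. With only 200 changed genes, the adjustment was stricter than in the real comparison, where 43.5% of genes were called. The recovered shares therefore do not give the sensitivity of the real comparison. A simulated list of 30 genes raised by 1 log2 unit was recovered, and 1 of 200 random lists had p below 0.05. The simulated genes varied independently of each other, whereas the estimated correlation within real lists reached 0.126. The simulation therefore cannot tell how often correlated lists are called falsely.

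Alternatives covered other floors, no floor, a pseudocount, no filter and a stricter filter, quantile normalization, median centring, other choices of probe set, separate tests of all probe sets, other variance models, array weights, the replicate number as a block, and leaving out each array. Differences of list medians outside the comparison were tested by permutation with fixed seeds. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, and tables were read with pandas 2.3.3.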

Results

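Gene expression was measured in macrophages made from THP-1, an established human monocytic leukaemia cell line that stops growing and attaches when treated with the phorbol ester PMA. The cells had received 160 nM PMA for 24 h and then 24 h without it. They were then stimulated either with 20 ng/ml interferon-gamma and 10 pg/ml lipopolysaccharide (LPS), the group M(LPS+IFNg), or with 20 ng/ml interleukin-4, the group M(IL4). Each group had 3 arrays, labelled as biological replicates, and each array held 54613 probe sets. No unstimulated macrophages are among the samples analysed here, so every difference is between the stimulated states and has no baseline. The share of probe sets above the signal floor was 57.2%, 59.1% and 60.2% in M(LPS+IFNg) and 57.1%, 60.5% and 66.0% in M(IL4). M(IL4) replicate 3 stood apart from the other 5 arrays with the highest share and the highest median signal (log2 6.58). Across genes, arrays of the same group correlated at r = 0.975 to 0.984 and arrays of different groups at 0.904 to 0.915, and 73.5% of the variance lay on the principal component that separated the groups. The number of arrays limits the precision of every value. The p-values of single genes rest on the spread between these 3 samples per group, combined with the spread of other genes by the moderated test.

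The comparison of M(LPS+IFNg) with M(IL4) addresses how the polarizing stimuli set apart macrophages of the same origin. Among genes measured on all 6 arrays, IDO1, which starts tryptophan breakdown, was 190-fold higher in M(LPS+IFNg) (log2 difference 7.57 ± 0.17 SE, n = 3 per group, limma adjusted p = 4.35e-13). IFI27 was 106-fold, GBP1 86.6-fold, ANKRD22 79.8-fold and SERPING1, the C1 inhibitor, 60.03-fold higher in the same group, and CD274 (PD-L1), AIM2 and PTGS2 (cyclooxygenase-2) were 58.5-fold, 49.7-fold and 43.1-fold higher. On the other side, CA2, a carbonic anhydrase, was 61.0-fold higher in M(IL4) (log2 difference -5.93 ± 0.08 SE, n = 3 per group, limma adjusted p = 7.72e-15). MS4A6A was 39.8-fold, LILRA2 30.5-fold, CTSG (cathepsin G) 28.4-fold, VCAN (versican) 25.8-fold, COLEC12 24.8-fold, SORL1 22.4-fold and ELANE (neutrophil elastase) 21.4-fold higher in M(IL4). Some of these folds rest on signals near the floor (log2 5.68) in the dimmer group. Examples are COLEC12 (mean 6.15) and VCAN (6.43) in M(LPS+IFNg), and CD274 (6.42), PTGS2 (6.48) and SERPING1 (6.48) in M(IL4).

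Some genes were above the floor in all 3 arrays of a single group and in none of the other, 58 of them on the M(LPS+IFNg) side and 83 on the M(IL4) side, and their folds are lower bounds. CXCL11 was at least 155-fold, IL32 at least 70.03-fold, ETV7 at least 35.04-fold, GBP1P1 at least 13.8-fold and ATP11A-AS1 at least 12.2-fold higher in M(LPS+IFNg). MS4A3 was at least 57.6-fold, SELENOP (selenoprotein P) at least 23.01-fold, CLSTN2 at least 10.7-fold, KIF18A at least 7.99-fold and TEDC2 at least 7.40-fold higher in M(IL4). GBP1P1 is a pseudogene close in sequence to GBP1, so its signal may not be its own.

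**Figure D1:**
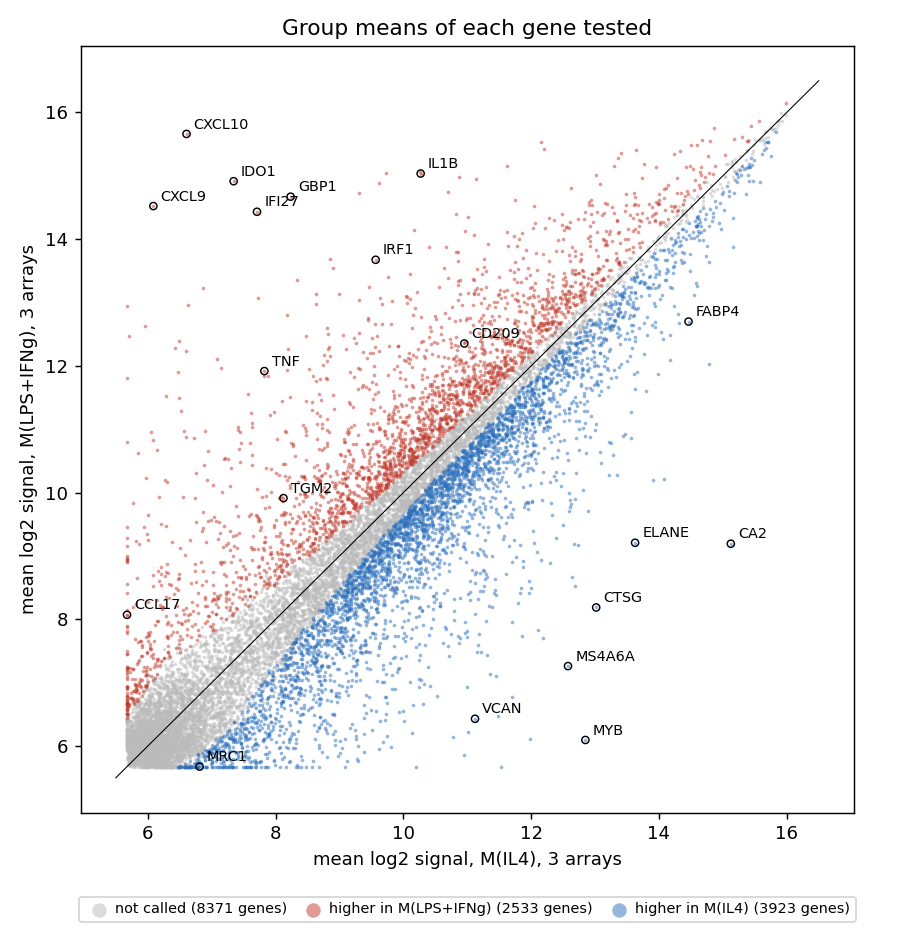
Mean log2 signal of each of the 14827 genes tested, M(IL4) on the horizontal axis and M(LPS+IFNg) on the vertical axis (3 arrays each), with the line of equal signal. Red points are the 2533 genes called higher in M(LPS+IFNg), blue points the 3923 called higher in M(IL4), grey points were not called, and CXCL10, CXCL9 and IDO1 lie furthest above the line among the genes labelled, and MYB and CA2 furthest below it.

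Of 14827 genes tested with limma, 6456 (43.5%) had a Benjamini-Hochberg adjusted p below 0.05, 2533 higher in M(LPS+IFNg) and 3923 higher in M(IL4). At least 2-fold apart were 2668 of them, 1084 and 1584 in the same order. In 7652 genes (51.6%) the values of the groups did not overlap, against 10% by chance for 3 arrays against 3. The share of calls that were higher in M(IL4) was 60.8% with the deposited scaling and 55.9% (3540 of 6329) with quantile normalization. After centring each array on its median it was 50% (3122 of 6246), a balance that centring brings about by construction. The median difference over all genes was -0.12 on the log2 scale, and centring moved it by 0.11. Of 27 gene lists fixed before the data were examined, camera with its preset correlation called 17, of which 15 were higher in M(LPS+IFNg) and 2 in M(IL4), and 9 held with an estimated correlation. For these 9, camera with an estimated correlation gave adjusted p-values of only 0.00326 to 0.0278, far above those with the preset correlation given below. Adjusted over the list alone, the member counts given next were the same in 19 lists, and the other 8 are given with their own counts.

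Interferon-inducible genes were higher in M(LPS+IFNg) almost without exception. In the interferon-gamma list, 29 of 33 measured members were higher in M(LPS+IFNg) and 3 were not called, with a list median of 3.53 on the log2 scale (11.6-fold, camera adjusted p = 6.86e-23). The chemokine genes CXCL10 and CXCL9, whose products attract T cells through CXCR3, were at least 531-fold (9.05 ± 0.37 SE) and at least 346-fold (8.43 ± 0.27 SE) higher. CXCL10 was above the floor in 2 and CXCL9 in 1 of the 3 M(IL4) arrays. The GTPase gene GBP5 was at least 82.2-fold higher, with 2 M(IL4) arrays above the floor (6.36 log2 units, and 5.76 without M(IL4) replicate 2). The transcription factor gene IRF1 was 17.3-fold and the cytokine signalling inhibitor gene SOCS1 at least 10.7-fold higher, SOCS1 with 1 M(IL4) array above the floor. The only member called higher in M(IL4) was IRF8, a transcription factor gene of the myeloid lineage, which was 2.47-fold higher there and was singled out after its value was seen. All 44 measured antiviral interferon-stimulated genes were higher in M(LPS+IFNg) (list median 2.95, camera adjusted p = 1.48e-31), among them IFI44L (at least 102-fold, 2 M(IL4) arrays above the floor) and IFIT3 (40.5-fold).

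Genes of antigen presentation were also higher in M(LPS+IFNg). For MHC class I, 16 of 19 members were higher and 0 lower (list median 1.13, camera adjusted p = 8.33e-10), led by the peptide transporter genes TAP1 (13.97-fold) and TAP2 (4.14-fold) and the immunoproteasome gene PSMB9 (4.55-fold). For MHC class II, 12 of 16 were higher in M(LPS+IFNg) and 2 in M(IL4) (list median 0.87, camera adjusted p = 5.39e-06), with HLA-DQA1 10.4-fold, HLA-DRA 7.93-fold and CD74, the invariant chain, 4.86-fold higher. The 2 exceptions, RFXAP and RFX5, encode subunits of the factor that binds class II promoters, and were 1.81-fold and 1.29-fold higher in M(IL4), named after their values were seen. CIITA, the class II transactivator, was near the floor and did not pass the test (0.40 ± 0.41 SE, adjusted p = 0.486). The costimulatory genes CD80 and CD86 were at least 9.59-fold and 1.98-fold higher in M(LPS+IFNg), CD80 with no M(IL4) array above the floor. HLA genes are so alike that their probe sets can read each other's transcripts.

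Inflammatory genes downstream of LPS and NF-kB were higher in M(LPS+IFNg) in 39 of 44 measured members (40 adjusted over the list alone), with a list median of 2.51 (5.71-fold, camera adjusted p = 1.07e-26). The cytokine genes IL1B and TNF were 27.2-fold (4.77 ± 0.06 SE) and 17.1-fold (4.09 ± 0.18 SE) higher, and IL6 was at least 29.9-fold higher with 1 M(IL4) array above the floor. CCL8 was at least 109-fold higher with 1 M(IL4) array above the floor, and the chemokine receptor gene CCR7 was 19.3-fold higher. IL12B, which encodes a subunit of IL-12, did not pass the test (0.90 ± 0.39 SE, adjusted p = 0.083), and passed it without M(IL4) replicate 3 (adjusted p = 0.0248). The single member higher in M(IL4) was IRAK3, an inhibitor of Toll-like receptor signalling (2.12-fold, named after its value was seen). Inflammasome and cell death genes were higher in M(LPS+IFNg) in 19 of 28 members (20 adjusted over the list alone) and higher in M(IL4) in 4 (list median 1.08, camera adjusted p = 3.32e-08). The DNA sensor gene AIM2 led them, with CASP5 at least 13.2-fold (2 M(IL4) arrays above the floor, 3.73 log2 units, and 3.10 without M(IL4) replicate 3) and the death ligand gene TNFSF10 11.1-fold higher. In tryptophan and arginine metabolism, 11 of 18 members were higher in M(LPS+IFNg) and 5 in M(IL4) (list median 1.36, camera adjusted p = 0.0011). The call was lost with an estimated correlation (adjusted p = 0.106 with an estimated correlation) and without _x_at and _s_at probe sets, where the median was 0.301 (adjusted p = 0.111). After IDO1, GCH1, which makes tetrahydrobiopterin, was 32.3-fold and WARS1, the tryptophanyl-tRNA synthetase, 11.6-fold higher. The arginine enzymes ARG1 and NOS2 did not pass the expression filter: no ARG1 probe set was above the floor in more than 2 of the 6 arrays, and the NOS2 probe set was above it in 1.

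Genes known to respond to interleukin-4 were split between the groups and, compared with other genes, did not differ as a list. Of 49 measured members of the IL-4 and STAT6 list, 19 were higher in M(IL4) (20 adjusted over the list alone), 11 were higher in M(LPS+IFNg) and 19 were not called, and the list was not called by camera (median -0.18, or -0.07 relative to the median of all genes, camera adjusted p = 0.898). Fry, which does not compare a list with other genes, placed it on the M(IL4) side (adjusted p = 0.00353). Higher in M(IL4) were MS4A6A, F13A1, the coagulation factor XIII A chain (at least 32.1-fold, 2 M(LPS+IFNg) arrays above the floor), MS4A4A (17.5-fold) and MRC1, the mannose receptor (at least 2.198-fold, 1.14 log2 units above a floor that no M(LPS+IFNg) array exceeded, adjusted p = 0.00876). Higher in M(LPS+IFNg) were the chemokine genes CCL17 (at least 5.26-fold, no M(IL4) array above the floor), CCL22 (3.65-fold, 1.87 ± 0.12 SE) and CCL18 (3.57-fold, 1.84 ± 0.34 SE), the transglutaminase gene TGM2 (3.46-fold, 1.79 ± 0.15 SE) and the lectin gene CD209 (2.64-fold, 1.40 ± 0.11 SE). CCL26, ALOX15, FCER2 and CISH did not pass the test (adjusted p = 0.342, 0.0598, 0.932 and 0.0943). FCER2 was at or near the floor on every array (mean log2 signal 5.72 in M(LPS+IFNg) and 5.69 in M(IL4)). CCL26 was at the floor in M(IL4) and near it in M(LPS+IFNg) (mean 6.03), so neither gene was shown to be equally expressed. ALOX15 was above the floor in the 3 M(IL4) arrays only, and passed on that side under 7 of 17 alternatives. Its difference of -0.79 became -2.59 with the floor at the 20th percentile (adjusted p = 0.00672) and -3.69 with no floor (0.0483), and it passed without M(IL4) replicate 3 (0.0371). CD163, a scavenger receptor gene often used as a marker of alternative activation, was 1.52-fold higher in M(LPS+IFNg) (adjusted p = 4.6e-05). Of the 29 tested genes of the fixed polarization panel, 20 were higher in M(LPS+IFNg), 3 (MRC1, PPARG and FABP4) were higher in M(IL4) and 6 were not called. The panel holds interferon and LPS genes such as CXCL9 and TNF beside interleukin-4 genes, so these counts do not describe interleukin-4 genes alone.

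**Figure D2:**
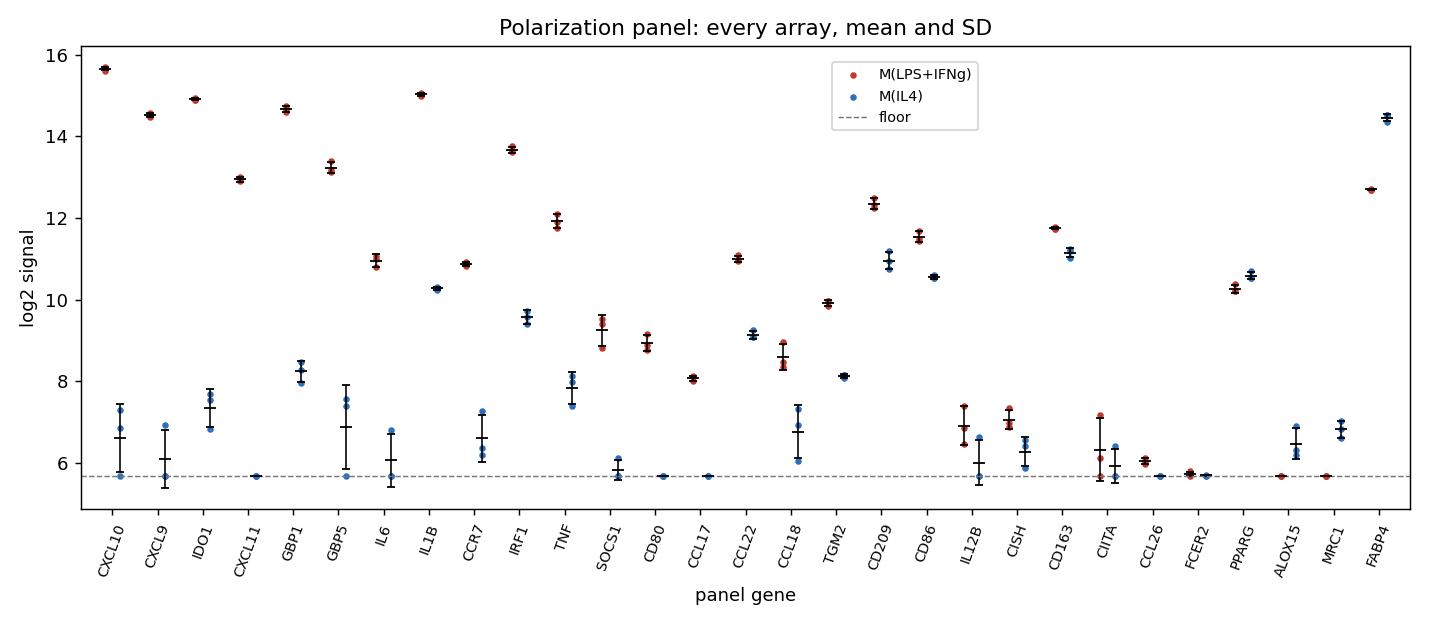
Log2 signal of the 29 polarization panel genes tested, ordered by their difference. Dots are single arrays (red M(LPS+IFNg), blue M(IL4), 3 each), bars the mean with its SD, and the dashed line the floor at log2 5.68; FABP4 at the right end is 3.39-fold higher in M(IL4), while CCL17, CCL22, CCL18, TGM2 and CD209 are higher in M(LPS+IFNg).

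Genes of the cell cycle were higher in M(IL4) throughout. All 44 measured members were called higher in M(IL4), with a list median of -2.91 on the log2 scale (7.53-fold, camera adjusted p = 4.95e-24). The mitotic genes ASPM (at least 27.7-fold, 2 M(LPS+IFNg) arrays above the floor), HMMR (17.8-fold) and DLGAP5 (16.7-fold) were furthest apart. The size for ASPM depends on the probe set, from -4.79 log2 units to -1.68 without _x_at and _s_at probe sets (adjusted p = 0.00212), which is less than for HMMR or DLGAP5. Markers of undifferentiated myeloid precursors lay on the same side: 10 of 15 were higher in M(IL4) and 0 in M(LPS+IFNg) (list median -1.65, camera adjusted p = 1.14e-06). The call held under every alternative, with medians from -1.58 with median centring to -3.80 without _x_at and _s_at probe sets. MYB, a transcription factor gene of haematopoietic progenitors, was at least 108-fold higher (-6.75 ± 0.27 SE), and PRTN3, which encodes the granule protease proteinase 3, at least 58.5-fold. Both were above the floor in 1 M(LPS+IFNg) array. MS4A3, CTSG and ELANE belong to the same list. The macrophage identity list lay slightly on the other side, with 13 of 22 members higher in M(LPS+IFNg) and 5 in M(IL4) (list median 0.28, or 0.39 relative to the median of all genes, camera adjusted p = 0.0208). Its call was lost with an estimated correlation (adjusted p = 0.149 with an estimated correlation) and without _x_at and _s_at probe sets (adjusted p = 0.0858). In that list CEBPB was 3.79-fold and NCF1, an oxidase subunit gene whose probe set also matches close paralogs, 38.7-fold higher in M(LPS+IFNg), and ITGAM, the CD11b integrin chain, was 5.85-fold higher in M(IL4). The ITGAM difference rests on a single probe set, since with probe sets ending in _x_at and _s_at left out another stood for the gene and showed no difference (0.045, adjusted p = 0.947).

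**Figure D3:**
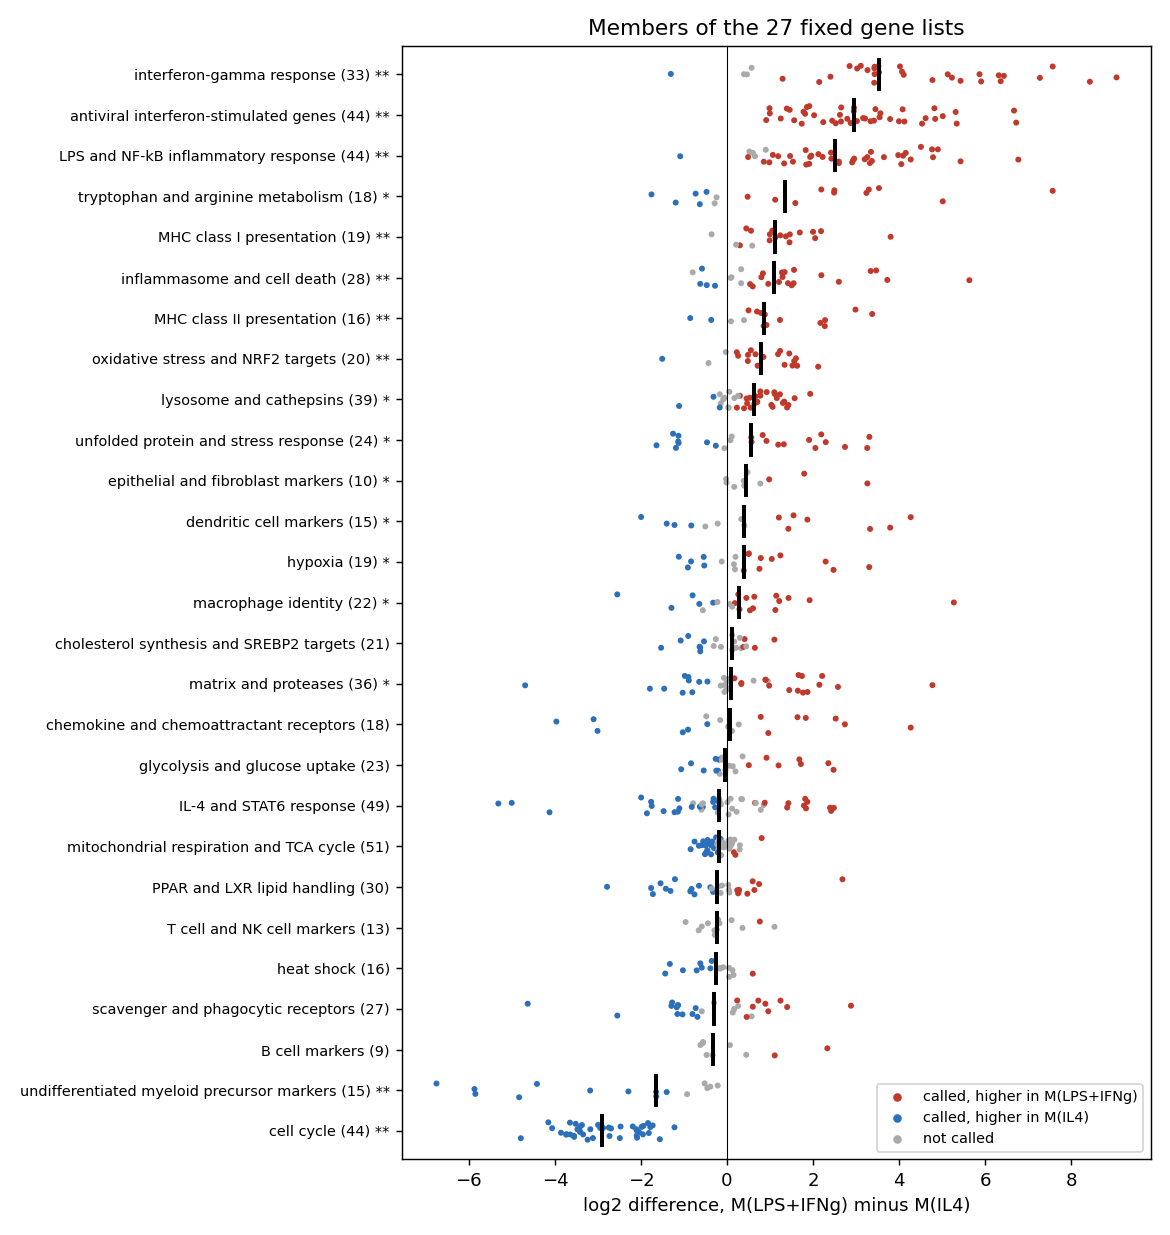
Log2 difference (M(LPS+IFNg) minus M(IL4)) of each measured member of the 27 fixed lists, with the number of members in brackets. Red and blue dots are members called higher in M(LPS+IFNg) and M(IL4), grey dots were not called, vertical bars are list medians, a single asterisk marks a list called by camera with its preset correlation and a double asterisk a list that also held with an estimated correlation, from interferon-gamma response (3.53) at the top to cell cycle (-2.91) at the bottom.

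Lists of lipid handling, cholesterol synthesis and glycolysis were split between the groups, and called members of the mitochondrial list were mostly higher in M(IL4). Camera called none of the 4. In PPAR and LXR lipid handling, 13 of 30 members were higher in M(IL4) (14 adjusted over the list alone) and 8 in M(LPS+IFNg) (median -0.22, or -0.11 relative to the median of all genes, camera adjusted p = 0.331). The lipoprotein lipase gene LPL and the fatty acid binding protein gene FABP4 were 6.90-fold and 3.39-fold higher in M(IL4), and NR1H3, the LXR-alpha receptor gene, was 6.43-fold higher in M(LPS+IFNg). PPARG was 1.25-fold higher in M(IL4) (adjusted p = 0.0255), and this call was lost when the arrays were centred on their median (adjusted p = 0.179) and without M(LPS+IFNg) replicate 1 (0.0826), M(LPS+IFNg) replicate 2 (0.0844) or M(IL4) replicate 2 (0.0953). In cholesterol synthesis, 7 of 21 members were higher in M(IL4), among them ACAT2 (2.89-fold) and EBP (2.11-fold), and 4 in M(LPS+IFNg) (5 adjusted over the list alone), among them LSS (2.15-fold). The median (0.12) and the mean (-0.11) of that list differ in sign (camera adjusted p = 0.993). In glycolysis and glucose uptake, 7 of 23 members were higher in each group (8 in each adjusted over the list alone). The median of that list was -0.04 and its mean 0.34, the median turned positive with quantile normalization (0.074) and with median centring (0.094), and camera gave an adjusted p of 0.19. The glucose transporter genes SLC2A3 and SLC2A6 were 5.12-fold and 3.29-fold higher in M(LPS+IFNg), and the hexokinase gene HK2 was 5.56-fold higher (2.48 log2 units, but 0.57 when the probe sets of the gene were averaged). In mitochondrial respiration, 24 of 51 members were higher in M(IL4) (26 adjusted over the list alone), such as NDUFB8 (1.80-fold) and NDUFB9 (1.69-fold), and 3 in M(LPS+IFNg), such as NDUFB3 (1.75-fold). That list had a median of -0.19, or -0.07 relative to the median of all genes, and was not called (camera adjusted p = 0.0537), though it passed under 9 of its 22 alternatives, always on the M(IL4) side, for example without M(IL4) replicate 3 (adjusted p = 0.0308) and with quantile normalization (0.00196).

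Stress lists leaned to M(LPS+IFNg) except heat shock. Of 20 measured NRF2 targets and oxidative stress genes, 17 were higher in M(LPS+IFNg) and 1 in M(IL4) (list median 0.78, camera adjusted p = 3.18e-07), led by the cystine transporter gene SLC7A11 (4.35-fold), PGD (3.10-fold) and NQO1 (3.04-fold). The PGD call was lost when the probe sets of the gene were averaged (adjusted p = 0.129). Hypoxia genes were higher in M(LPS+IFNg) in 10 of 19 members, such as ADM (9.89-fold) and VEGFA (4.91-fold), and higher in M(IL4) in 5 (list median 0.39, camera adjusted p = 0.017), a call that was lost with an estimated correlation (adjusted p = 0.106 with an estimated correlation). It was also lost without _x_at and _s_at probe sets, where the median was 0.011 (adjusted p = 0.183). The unfolded protein and stress list had 13 of 24 members higher in M(LPS+IFNg) and 8 in M(IL4) (list median 0.57, camera adjusted p = 0.0194), and this too was lost with an estimated correlation (adjusted p = 0.171 with an estimated correlation) and with quantile normalization (adjusted p = 0.0679). ASNS, the asparagine synthetase gene, was 9.91-fold, CHAC1, which degrades glutathione, 9.58-fold and DDIT4, an mTORC1 inhibitor gene, 6.70-fold higher in M(LPS+IFNg). In the heat shock list, 8 of 16 members were higher in M(IL4) and 1 in M(LPS+IFNg) (median -0.26, or -0.14 relative to the median of all genes, camera adjusted p = 0.118). The chaperone genes HSPB1, HSPD1 and HSPE1 were 2.70-fold, 2.51-fold and 2.03-fold higher in M(IL4), and the HSPD1 call was lost without _x_at and _s_at probe sets (adjusted p = 0.0622).

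Lysosomal genes were higher in M(LPS+IFNg) in 27 of 39 members and higher in M(IL4) in 3 (4 adjusted over the list alone), with a list median of 0.63 (camera adjusted p = 1.12e-07). The list call was lost with an estimated correlation (adjusted p = 0.0884 with an estimated correlation). The cathepsin genes CTSK and CTSD and the fucosidase gene FUCA1 were 3.82-fold, 2.98-fold and 2.69-fold higher. Scavenger and phagocytic receptors were split, with 12 of 27 higher in M(IL4), led by COLEC12, and 9 in M(LPS+IFNg), led by SIGLEC1 (7.37-fold). The median of that list was -0.30 and its mean -0.29, camera placed it on the M(LPS+IFNg) side (adjusted p = 0.991), and it was not called. In the matrix and protease list, 16 of 36 members were higher in M(LPS+IFNg), with the macrophage elastase gene MMP12 27.4-fold and the collagenase gene MMP1 5.98-fold higher, and 10 were higher in M(IL4), led by VCAN (median 0.10, camera adjusted p = 0.0245). That call was lost with an estimated correlation (adjusted p = 0.149 with an estimated correlation). Chemokine and chemoattractant receptors also split, 7 of 18 higher in M(LPS+IFNg), led by CCR7, and 6 in M(IL4), led by CCR2 (15.6-fold) and CXCR2 (8.57-fold), and the list was not called (median 0.07, camera adjusted p = 0.173).

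Markers of other cell types gave few calls, apart from those of dendritic cells. All samples came from a single cell line, so these calls do not show that other cell types were present. Of 13 T and NK cell markers, only NKG7 was called (1.70-fold higher in M(LPS+IFNg), list median -0.24, mean -0.11, camera direction M(LPS+IFNg), adjusted p = 0.993), and of 9 B cell markers EBF1 (5.04-fold) and PAX5 (2.16-fold) were called higher in M(LPS+IFNg) (list median -0.33, mean 0.16, camera adjusted p = 0.815). The PAX5 call (adjusted p = 0.0251) was lost without any 1 of 5 arrays, with an adjusted p of up to 0.102 without M(IL4) replicate 1. Of 15 dendritic cell markers, 7 were higher in M(LPS+IFNg) and 4 in M(IL4). Among the 7 were CCR7 (19.3-fold), which is also in the chemokine receptor list, LAMP3 (13.9-fold) and the chemokine gene CCL19 (10.0-fold). The list was called with a median of 0.41 (camera adjusted p = 0.0433). This call was lost with an estimated correlation (adjusted p = 0.149 with an estimated correlation) and without M(LPS+IFNg) replicate 1 (0.0546) or M(IL4) replicate 3 (0.0566), and also with the floor at the 60th percentile (0.072) and with no filter on dim probe sets (0.0725). Of 10 epithelial and fibroblast markers, PDGFRA (at least 9.60-fold, 1 M(IL4) array above the floor), DCN (at least 3.47-fold, 2 above) and LUM (at least 1.97-fold, 0 above) were called higher in M(LPS+IFNg) and none in M(IL4) (list median 0.44, camera adjusted p = 0.0192). The list call was lost with an estimated correlation (adjusted p = 0.11 with an estimated correlation). It was also lost with the floor at the 20th percentile, where the median was 0.017 (adjusted p = 0.471), with no filter on dim probe sets (0.198) and without _x_at and _s_at probe sets (0.132). DCN lost its call without _x_at and _s_at probe sets (adjusted p = 0.323), and LUM (adjusted p = 0.0356) lost its call under 9 of 17 alternatives.

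Signals of a gene's probe sets did not always point the same way. Of 3681 called genes with another tested probe set, 2075 had a further probe set called the same way and 110 a further one called the opposite way. Among the 113 genes picked by the naming rule, none had a further probe set called the opposite way. Sizes still depended on the probe set: with the probe sets of a gene averaged, the log2 difference of MYB was -4.11, of MS4A6A -4.14, of LILRA2 -3.38 and of SORL1 -3.14, that of GBP1 4.92, of CD274 4.54, of SOCS1 1.63 and of ATP11A-AS1 1.47, and CXCL11 was at 4.93 without _x_at and _s_at probe sets. ANKRD22 was at 4.67 with quantile normalization.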

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

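All alternatives were chosen before the data were examined, except the mitochondrial list without COXFA4, added afterwards. The count of 6456 genes stayed within 1.5 times under every alternative at the gene level, from 4608 without _x_at and _s_at probe sets (fewer genes were tested) to 6628. Testing all probe sets separately gave 11884 calls among 33786 probe sets, because more units were tested. Leaving out each array gave 5731 to 6132 genes, 2585 to 2690 at least 2-fold apart, and 86.9% to 89.9% of the 6456 genes were called again. Camera with an estimated correlation called 9 lists in place of 17. Fry called 25; it tests whether genes move, on balance, to a single side and does not compare a list with other genes. It added the IL-4 and STAT6 list (adjusted p = 0.00353), lipid handling (0.000308), heat shock and mitochondrial respiration (0.000595 each) on the M(IL4) side. It also added glycolysis (0.00187) and chemokine receptors (0.00779) on the M(LPS+IFNg) side. Fry called 2 lists on the other side from where camera had placed them without a call. They were cholesterol synthesis (median 0.121) and scavenger receptors (median -0.3), both on the M(IL4) side, and the mean of both lists is negative. Fry measures a list against 0 and camera against the other genes, and the median of all genes was -0.12, towards M(IL4). This offset also bears on the lists that fry added on that side, and its share in either result was not tested. T cell and NK cell markers also changed side but were called by neither (fry adjusted p = 0.552). ITGAM went from -2.55 to 0.045 without _x_at and _s_at probe sets, since another probe set then stood for the gene. The mitochondrial list passed under 9 of its 22 alternatives, among them the one without COXFA4 (adjusted p = 0.046), with the highest adjusted p at 0.399. Over named genes and alternatives, 2040 results were on the same side of the test in the same direction, 24 were no longer called, 14 were newly called and 1 turned. For lists these counts were 529, 20, 14 and 2.

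With the replicate number as a block, 6628 genes were called, 2689 of them at least 2-fold apart, and the dendritic cell list was lost (adjusted p = 0.0532), while IL12B passed (adjusted p = 0.0444). Deviations of same-numbered arrays from their group means correlated at 0.081, 0.017 and 0.099 across genes. These values are low, and whether the numbers pair the samples was not tested. Each value was above the best correlation with another number. Array medians also rose with the replicate number in both groups (log2 6.09, 6.19 and 6.25 in M(LPS+IFNg), and 6.09, 6.29 and 6.58 in M(IL4)). Both are hints of a shared replicate effect from the data and not from the design.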

Other observations

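The tests of the amino acid response, endoplasmic reticulum genes, cell cycle phases and neighbouring genes were set out before their results were seen. The added gene lists were drawn up after the fixed lists had been read. Those of metallothioneins and ribosome biogenesis were drawn up before their members' values were seen, but no direction or condition was written down for them. The other tests of this part were chosen only after the results were seen. All 7 measured metallothionein genes, which encode metal-binding proteins, were higher in M(LPS+IFNg), from 2.67-fold for MT1E to at least 9.80-fold for MT1M (median 1.94, camera adjusted p = 1.87e-07, and 0.0413 with an estimated correlation). They are close paralogs whose probe sets can read each other. The complement group was drawn up after C1QB, a gene of the same complex as C1QA and C1QC, had been seen to be higher in M(LPS+IFNg), so no test is given for it. C1QB was left out from the start, and 4 members of the fixed lists were left out after a first result. Of the other 14 complement genes, 7 were higher in M(LPS+IFNg), among them C1QC (4.75-fold), C1QA (4.36-fold) and C2 (4.27-fold), while C5 (4.08-fold) and CFD (1.53-fold) were higher in M(IL4). With C3AR1, CR1, ITGAX and VSIG4 kept, 8 of 18 were higher in M(LPS+IFNg) and 3 in M(IL4). Of 29 ribosome biogenesis genes, 19 were higher in M(IL4), among them UTP20 (2.99-fold), NOP16 (2.39-fold) and FBL (2.39-fold), and only NOP10 (1.21-fold) in M(LPS+IFNg) (median -0.58, camera adjusted p = 2.9e-05, and 0.0149 with an estimated correlation).

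The unfolded protein and stress list held members on both sides, amino acid response genes such as ASNS in M(LPS+IFNg) and chaperone genes such as HSP90B1 in M(IL4), the latter named after its value was seen. A hypothesis is that the amino acid response driven by ATF4 was more active in M(LPS+IFNg). Among 33 further ATF4 targets, 27 were higher in M(LPS+IFNg) and 3 in M(IL4), with a median of 0.93 (camera adjusted p = 6.42e-12, and 0.00661 with an estimated correlation). CTH (11.7-fold), NUPR1 (6.63-fold), PCK2 (5.504-fold) and PSAT1 (4.75-fold) were furthest apart. A second hypothesis, that genes of folding and translocation in the endoplasmic reticulum may be higher in M(IL4), stayed undecided: 19 of 30 were higher there and 4 in M(LPS+IFNg), with a median of -0.35 (-0.45 with quantile normalization and -0.22 with median centring). Camera called the list with its preset correlation (adjusted p = 0.00603) but not with an estimated correlation (adjusted p = 0.178), which had been set as the condition.

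The first weighed pattern is that cell cycle and precursor granule genes were higher in M(IL4). Scaling argues against itself as the source, since the cell cycle median was -2.78 or lower under quantile normalization and median centring, and no single M(IL4) array carries it, since the median was -2.90 or lower with each left out. A larger share of undifferentiated cells in the M(IL4) cultures may account for it and cannot be told apart from an effect of the stimuli. The macrophage identity list would then be lower in M(IL4). Its median of 0.28 goes that way, but the call was lost by camera with an estimated correlation (adjusted p = 0.149). The stimuli may themselves change members of that list, so it cannot decide the question. LYZ, picked after its value was seen, was 2.44-fold higher in M(IL4), and a single gene cannot decide it either. An effect of interferon-gamma and LPS on proliferation, or of interleukin-4, stays open and untested without unstimulated cells.

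Within the cell cycle, genes of G2 and M phase may differ more than genes of S phase. Among 32 G2 and M genes and 30 S phase genes outside the fixed list, the medians were -2.65 and -1.90, a difference of -0.75 (two-sided permutation test over genes, 100000 resamples, p = 0.00244). Genes are not independent replicates, so this p describes these lists only. SPC24 (11.1-fold) and GTSE1 (10.0-fold) led the former group, MCM10 (at least 8.51-fold) and ATAD2 (7.42-fold) the latter.

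The second weighed pattern is the split of the IL-4 and STAT6 list, with CCL17, CCL22, CCL18, TGM2 and CD209 higher in M(LPS+IFNg). Exchanged group labels are excluded as the source, since 29 of 33 interferon-gamma genes were higher in the arrays labelled M(LPS+IFNg). Of the 11 members higher in M(LPS+IFNg), 7 had another tested probe set. Of their 11 further probe sets, 9 were called the same way and 0 the opposite way. For the 6 members these 9 belong to, this argues against probe sets reading another gene. It does not cover further probe sets that read the same other gene, which was not checked. For CLEC4A, whose only further probe set was not called, and for the 4 members without a further probe set (BATF3, CCL17, CCL22 and CLEC10A), the reading of another gene stays open. Induction of the members higher in M(LPS+IFNg) by LPS or interferon-gamma, or a weak response to interleukin-4, may explain the split. CCL17 and CCL26 were at the floor on all 3 M(IL4) arrays and FCER2 at or near it. No rise of these genes above that working limit was therefore seen with interleukin-4. On the other side, 19 list members were higher in M(IL4). For genes with signal in both groups, neither explanation was tested, since no unstimulated cells are among the samples.

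Tested genes next to each other in the genome shared a direction more often than chance. Among 500 neighbouring pairs of 2-fold genes with different symbol stems, 66.6% had the same direction, more than in any of 10000 shuffles of the directions, whose mean was 51.7% (permutation test, one-sided p = 1e-04, the smallest they can give). With families of like symbols included, 69.6% of 582 pairs did. Runs of neighbours higher in M(LPS+IFNg) included IFIT2, IFIT3, IFIT1 and IFIT5 (median 4.47) and APOL3, APOL4, APOL2 and APOL1 (median 3.04), and PLPPR3, AZU1, PRTN3 and ELANE (median -3.47) formed a run higher in M(IL4). Related genes with unlike symbols remain among these pairs, so shared control of neighbours is a hypothesis.

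The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 6456 genes, 2668 of them at least 2-fold apart, and limma called 0 genes in each of the others, which had at most 382 genes at an unadjusted p below 0.05. These others mix the groups, so the difference between the groups adds to the spread within each side and lowers the number of calls. Their 0 calls therefore do not measure what chance would give. Only 1 of the 10 splits, the real one, gave as many genes, as many 2-fold genes or as many lists. Camera with its preset correlation called 17 lists in the real split and up to 12 in the others, each of which sets 2 arrays of a group and 1 of the other against the rest and so keeps part of the difference between groups. Of genes whose probe sets disagree, SH3BP2 was 1.61 ± 0.10 SE by its chosen probe set and -1.33 ± 0.40 SE by another, and ZC3HAV1 -0.90 ± 0.11 SE and 1.30 ± 0.16 SE, on the log2 scale.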
